A study of Rattus norvegicus with 2 samples.

How the data were processed

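MicroRNA (miRNA) levels were measured on 1-colour arrays with total RNA labelled with Cy3 by an Agilent miRNA reagent, from rat carotid artery, per the labels' protocols. There were 2 arrays, 1 from an artery that was not injured and 1 from an artery taken 10 days after balloon injury, so each group held 1 array. Balloon injury is a standard rat model in which an inflated catheter strips the endothelium and stretches the wall, after which smooth muscle cells divide and form a neointima. The animals were male Sprague-Dawley rats of about 250 g, per the labels. How many rats contributed to each RNA sample is not given in the sources used here. RNA was extracted with Trizol and its quality was checked on a Bioanalyzer, per the labels' protocols.

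The deposited array files give 1 signal intensity and 1 flag for each of 350 rat miRNA features and 22 control features. The intensities are on a linear scale. The scanner software, the background subtraction and any normalization before deposit are not given in the sources used here. On each array 109 miRNAs were listed at exactly 1, which reads as a floor put in place of values at or under 0, and a further 27 (uninjured) and 24 (injured) undetected miRNAs lay under 1. The flag was 0 on all 7 negative control features of both arrays and 1 on the 6 brightest control features of both arrays, so it was read as detection, although the deposited files do not define it. The deposited value table of the series holds a linear ratio per miRNA, with its scale unstated. Its injured column equalled the injured intensity divided by the uninjured intensity, within a relative tolerance of 1e-05, for 349 of the 349 names shared with the array files (1 further name carried a database suffix in the table only). Its uninjured column was 1 within that tolerance for every miRNA, and the median of the injured column was 1. It is therefore a ratio without scaling between arrays, and served as an alternative.

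A miRNA was called measured on an array when its flag was 1. Intensities were put on the log2 scale and scaled by subtracting each array's 75th percentile over the 158 miRNAs measured on both arrays, which lay at an intensity of 401 on the uninjured and 377 on the injured array. The scaling raised every log2 ratio by 0.09. The log2 ratio is injured minus uninjured throughout. For a miRNA measured on 1 array only, the ratio is a bound, written "at least": the bright array's value was set against the higher of the dim array's lowest detected signal and the miRNA's own dim signal. The lowest detected intensity was 3.43 on the uninjured array and 1.36 on the injured array, and 11 detected miRNAs on each array lay at or under the highest undetected intensity (8.84 and 5.98), so bounds were also computed against that highest undetected signal. Control features were left out of the scaling and of the counts.

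With 1 array per group no replicate error could be computed, no test of a difference between the groups was run and no p-value is given. A difference of 2-fold was used as a descriptive threshold. The number of arrays limits the precision.

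The 22 miRNA lists (smooth muscle contractile, smooth muscle proliferation, leukocyte, erythroid, endothelial, striated muscle, nerve, epithelial, liver, adipose, hypoxia, the Dlk1-Dio3 imprinted region and families or clusters) were fixed before the data were examined, as were the comparisons, the named-miRNA rule and the alternatives, except those said to be added later. The smooth muscle proliferation list was drawn from general knowledge of injured or cultured arteries. Some miRNAs stand in more than 1 list, such as miR-1, miR-133a and miR-133b in the contractile and striated muscle lists. For a list with at least 3 members measured on both arrays, the median log2 ratio was ranked among 10000 random lists of the same size matched on 4 bins of mean signal. This percentile describes these 2 arrays and is not a p-value; uniform scaling does not move it. On simulated data for the 158 miRNAs, with a noise SD of 0.4 on the log2 scale, lists of 5 miRNAs shifted by 1 log2 unit fell outside the middle 95% of random lists in 100% of 200 simulations, and unshifted ones in 5%. The simulated noise was independent between miRNAs, whereas some list members share a transcript or a similar sequence. The real log2 ratios also spread more widely than this noise, from -2.47 to 2.565. These rates therefore need not hold for the real lists, and the 100% may be too high. In a simulation without noise, with an array factor of 1.7 and 20 miRNAs changed 4-fold, all 20 and no others were called. Without noise no other miRNA could be called, so this checks the computation and gives no rate of false calls. The median of the unchanged miRNAs moved by 0.0017 with 10 raised and 10 lowered, and by -0.38 with all 20 raised, so the scaling is shifted when changes run mostly one way.

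The named miRNAs are the 12 highest and 12 lowest log2 ratios among those measured on both arrays and in the brighter 75% (119 miRNAs), the up to 6 brightest measured on 1 array only, the 5 brightest of each array, and any member of the lists. The alternatives were scaling to the 75th percentile of all 350 miRNAs, to the median, or not at all; quantile normalization; the value table; a filter to the brighter miRNAs; a pseudocount of 1; thresholds of 1.5-fold and 4-fold; and detection at over 2 times the floor. Scaling to the control features, the stricter bounds, dim signals of miRNAs measured on both arrays raised to the highest undetected signal, and list medians with either kind of bound were added after the data were seen. The rat gene table (assembly GRCr8) was used only to find which miRNA genes lie within 10 kb of each other. The array build is not given in the sources used here, so no coordinates are reported. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.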

Results

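The miRNA content of a rat carotid artery taken 10 days after balloon injury was compared with that of a carotid artery that had not been injured, to find which miRNAs differ in the remodelling vessel wall. Each group held 1 array, so the values below have no replicate error and compare these 2 arrays. Of 350 rat miRNAs, 166 were measured on the uninjured array and 184 on the injured array. Of the 350, 158 were measured on both, 26 only on the injured array and 8 only on the uninjured array, while 158 were measured on neither. The summed miRNA signal was 95491 on the uninjured and 97479 on the injured array. Detected signals ran from 3.43 to 17014 on the uninjured array and from 1.36 to 13992 on the injured array.

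The brightest signals were largely shared; brightness also depends on the probe, so its order is not an order of abundance. miR-143, a miRNA of smooth muscle, was the brightest on both arrays, with 17.8% of the summed miRNA signal on the uninjured array and 14.4% on the injured array. It was followed on the uninjured array by let-7c, miR-125b-5p, miR-23b and let-7a. On the injured array let-7c, miR-21, miR-125b-5p and miR-23b followed it. Among the 20 brightest miRNAs by summed signal, 19 differed by under 1.5-fold between the arrays, and the exception was miR-21. That count depends on the scaling. With the control features aligned, others among them were also lower by over 1.5-fold, such as miR-143 (log2 ratio of -0.79), miR-23b (-0.74) and miR-125b-5p (-0.62). Log2 signals of the 158 miRNAs correlated with Pearson's r = 0.96 across miRNAs, which are not independent replicates.

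In the injured artery 20 of the 158 miRNAs were at least 2-fold higher and 6 were at least 2-fold lower, and 102 lay within 1.5-fold. The median log2 ratio was 0.14, with quartiles of -0.14 and 0.58. The balance of higher to lower depended on the scaling: with the arrays aligned at their medians 8 were higher and 16 lower, with quantile normalization 12 and 11, with the 75th percentile of all miRNAs 7 and 20, and with the control features aligned 7 and 23. Without scaling the split was 17 and 7. These scalings shifted the log2 ratios of the 158 miRNAs by a median of -0.44, -0.30, -0.50, -0.59 and, without scaling, -0.09, and the percentiles given for lists compare members with other miRNAs of like signal. Under each of them 7 miRNAs stayed at least 2-fold higher, namely miR-146b, miR-142-5p, miR-17-5p, miR-21, miR-142-3p, miR-20a and miR-223, and each of the other higher ones was under 2-fold in at least 1 of them. The same 6 miRNAs stayed at least 2-fold lower under each, namely miR-451, miR-1, miR-494, miR-144, miR-133a and miR-133b. Each of these scalings moved the ratios down, in the median under quantile normalization. The scaling used here thus gave the most higher and the fewest lower calls. Except under quantile normalization, no lower call could be lost, so keeping the 6 adds little support.

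**Figure D1:**
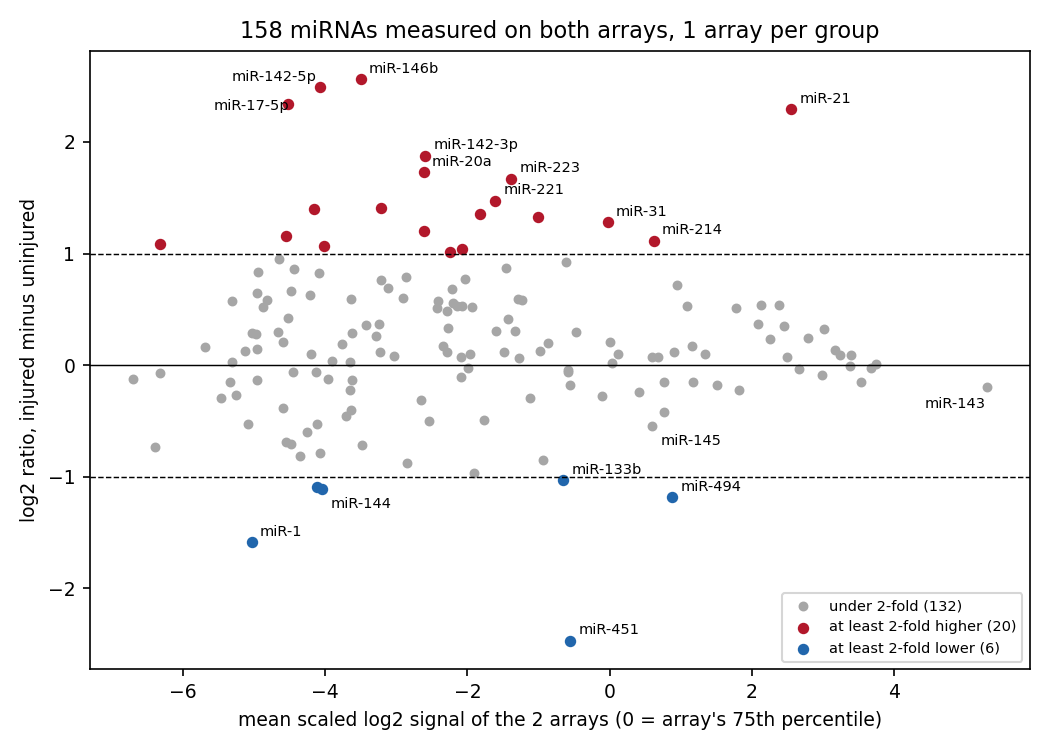
Each point is a miRNA measured on both arrays, with its mean scaled log2 signal on the x axis and its log2 ratio (injured minus uninjured) on the y axis; dashed lines mark 2-fold. miR-21 stands out among the bright miRNAs with a log2 ratio of 2.29, and miR-451 is the lowest at -2.47.

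Most measured miRNAs of the smooth muscle proliferation list were higher in the injured artery. Of the 10 members of this list measured on both arrays, 6 were at least 2-fold higher and none was at least 2-fold lower. miR-146b, of a family that dampens innate immune signalling, was 5.92-fold higher, with signals of 14.6 and 81.0. miR-21, a miRNA known to favour smooth muscle growth, was 4.90-fold higher, with signals of 1065 and 4915. The clustered miR-221 and miR-222, which repress the cell-cycle inhibitor p27, were 2.78-fold and 2.02-fold higher. miR-31 was 2.44-fold and miR-214 2.17-fold higher. The passenger strand miR-21* was measured only in the injured artery, at least 3.64-fold higher (1.41-fold against the highest undetected signal). miR-146a had a log2 ratio of 0.77, while miR-24 (0.09), miR-352 (-0.02) and miR-26a (-0.08) lay near 0. The list's median log2 ratio was 1.07, at percentile 99.98 of random lists matched on signal. With the control features aligned it was 0.48. miR-222 was under 2-fold in every other scaling, miR-31 and miR-214 with the medians aligned, with the 75th percentile of all miRNAs and with the control features aligned, and miR-221 in the last 2 of these; miR-214 was also under 2-fold with quantile normalization. miR-146a also stands in the leukocyte list, whose median log2 ratio was 1.22. Which cells carry the members of the proliferation list was not tested. Because the list was drawn from general knowledge of injured or cultured arteries, its percentile is not a measure of proliferation.

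The miR-17-92 cluster and its paralogs, which are abundant in dividing cells, were higher in the injured artery in every member measured on both arrays. All 7 had a positive log2 ratio and 5 were at least 2-fold higher, of which miR-17-5p and miR-20a stayed so under every scaling. miR-17-5p was 5.06-fold higher (signals of 7.78 and 37.1, and at least 4.46-fold against the highest undetected signal, under which the lower one lies), miR-20a 3.32-fold, miR-93 2.65-fold, miR-19b 2.55-fold and miR-92a 2.30-fold. miR-106b and miR-25 were 1.83-fold and 1.61-fold higher. Members measured only in the injured artery were miR-19a, at least 4.62-fold higher, and miR-18a, at least 3.39-fold higher. Against the highest undetected signal these bounds were 4.26-fold and 1.32-fold. The list's median log2 ratio was 1.35, at percentile 99.9, and 0.76 with the control features aligned, where miR-93 (0.81), miR-19b (0.76) and miR-92a (0.61) were under 2-fold, as they were with the 75th percentile of all miRNAs and with the medians aligned, and miR-19b and miR-92a also with quantile normalization. miR-17-5p, miR-20a, miR-93 and miR-106b are closely similar in sequence, so their probes cannot be assumed to separate them. miR-19a, miR-19b and miR-92a are not of that sequence group, but whether probes separate miR-19a from miR-19b was not tested either. The leukocyte list was also higher, with a median log2 ratio of 1.22, and which cells carry the miR-17-92 members was not tested.

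Leukocyte miRNAs were higher and red-cell miRNAs were lower in the injured artery. In the leukocyte list 3 of 6 members measured on both arrays were at least 2-fold higher: miR-142-5p at 5.61-fold, miR-142-3p at 3.67-fold and miR-223, a miRNA of neutrophils and macrophages, at 3.19-fold. miR-146a was 1.71-fold higher and miR-342-3p had a log2 ratio of 0.19 (-0.40 with the control features aligned), whereas miR-150, a miRNA of mature lymphocytes, had a log2 ratio of -0.50. The leukocyte median log2 ratio was 1.22, at percentile 99.56. miR-142-5p and miR-142-3p are both arms of 1 hairpin, so the calls and the percentile count that hairpin more than once. The erythroid miRNAs miR-451 and miR-144, which are made from 1 transcript, were 5.53-fold lower (signals of 641 and 109) and 2.16-fold lower. The endothelial miR-126 and miR-126* had log2 ratios of 0.08 and -0.22, and that of miR-126 was -0.51 with the control features aligned.

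All 5 members of the smooth muscle contractile list were lower in the injured artery, 3 of them by at least 2-fold. The 3 were miR-1 with a log2 ratio of -1.58, miR-133a at 2.13-fold lower and miR-133b at 2.05-fold lower, which are also the myomiRs of heart and skeletal muscle. miR-143 and miR-145, a cluster known to be abundant in smooth muscle, had log2 ratios of -0.19 and -0.55. Over the scalings miR-143 ranged from -0.79 to 0 and miR-145 from -1.14 to -0.54, with miR-145 at least 2-fold lower with the 75th percentile of all miRNAs (-1.05) and with the control features aligned. The list's median log2 ratio was -1.03, at percentile 0.025. That median and the 3 calls came from miR-1, miR-133a and miR-133b, while miR-143 and miR-145 moved less. In the striated muscle list, which shares miR-1, miR-133a and miR-133b, the further member miR-499 had a log2 ratio of -0.29, and the median of 4 was -1.06, at percentile 0.02. The skeletal muscle miR-206 and the cardiac miR-208 were measured on neither array. miR-133a and miR-133b are near-identical in sequence, so their probes cannot be assumed to separate them. With these members shared, the lists cannot tell smooth from striated muscle. The leukocyte median log2 ratio was 1.22, and a change in cell composition was not told apart from a change within smooth muscle cells.

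Of the 8 measured miRNAs of the nerve list, 5 were detected only in the uninjured artery. They make up 5 of the 8 miRNAs measured only on that array: miR-124, a neuron-specific miRNA, was at least 11.2-fold lower after injury, miR-138 at least 7.96-fold, miR-9* at least 5.11-fold, miR-129* at least 3.98-fold and miR-9 at least 2.60-fold. The brightest miRNA measured only there, miR-137, which is also abundant in neurons, had a signal of 55.5 and was at least 38.3-fold lower. miR-598-3p was at least 2.89-fold lower. miR-338, a miRNA of neurons and myelinating glia, was measured on both arrays and was 1.81-fold lower. miR-128 had a log2 ratio of 0.36 (-0.23 with the control features aligned), and miR-219-5p, a miRNA of myelinating glia, was measured only in the injured artery, at least 5.12-fold higher. The 8 measured members, with bounds for those on 1 array, had a median of -1.69, below all 10000 random lists matched on signal, and -0.54 at percentile 0.185 against the highest undetected signal. Both floors were lower on the injured array, at 1.36 against 3.43 and at 5.98 against 8.84. Bounds for miRNAs measured only on the uninjured array could thus run larger, which pulls these medians down. The uninjured signals of miR-9 and miR-129*, 7.43 and 5.77, were under that array's highest undetected signal of 8.84. Against the highest undetected signal the bounds were smaller, at 8.74-fold for miR-137, 4.19-fold for miR-138, 2.56-fold for miR-124, 2.02-fold for miR-9*, 1.20-fold for miR-598-3p and 1.17-fold for miR-9, with no bound above 1 for miR-129*, and miR-219-5p was at least 3.71-fold higher.

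Among the other miRNAs measured only in the injured artery, the 6 brightest included miR-34b, a p53-responsive miRNA, which was at least 6.47-fold higher, miR-132, at least 5.51-fold higher, miR-450a, at least 3.53-fold higher, and miR-455, at least 2.19-fold higher. Against the highest undetected signal the bounds were 2.51-fold for miR-34b, 2.14-fold for miR-132, 1.93-fold for miR-450a and 2.19-fold for miR-455. Other low ratios set by the naming rule were miR-494 at 2.27-fold lower (signals of 1111 and 461), miR-218 at 1.95-fold, miR-188 at 1.84-fold, miR-181c at 1.73-fold, miR-328 at 1.64-fold and miR-466b at 1.44-fold lower. miR-15b, of the miR-15/16 seed family, was 2.51-fold higher.

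All 8 let-7 family members lay between -0.03 and 0.23 on the log2 scale, with a median of 0.09 at percentile 43.2, and that median was negative under every other scaling. The miR-23, miR-27 and miR-24 clusters had a median of 0.09 (percentile 46.5), the miR-30 family 0.12 (percentile 51.6), the miR-181 family 0.13 (percentile 37.5) and the miR-29 family, which targets collagens and elastin, 0.03 (percentile 33.7). Those 4 medians were negative with the arrays aligned at their medians. Members of the miR-181 family went both ways, from -0.79 for miR-181c to 0.69 for miR-181b, as did those of the miR-29 family, from -0.69 for miR-29c* to 0.54 for miR-29b. The miR-99, miR-100, miR-125 and miR-10 families had a median of -0.03 (percentile 10.9). The miR-15/16 seed family had a median of 0.54 (percentile 93.6), which was -0.055 with the control features aligned, and its members miR-195 and miR-497 were both at -0.15. The transcript of miR-199a and miR-214 had a median of 0.72, at percentile 98.3, from miR-214, miR-199a-5p (1.65-fold higher) and miR-199a-3p (log2 ratio of 0.37, and -0.22 with the control features aligned).

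In the imprinted Dlk1-Dio3 list, 11 of 15 members measured on both arrays had a positive log2 ratio and 2 were at least 2-fold higher, miR-379 at 2.64-fold and miR-136 at 2.09-fold, while miR-494 was lower. miR-136 was under 2-fold in every other scaling, with a lowest log2 ratio of 0.47, and miR-379 with the medians aligned, the 75th percentile of all miRNAs or the control features aligned (0.81), while miR-494 was at least 2-fold lower under every scaling. The list's median of 0.43 lay at percentile 92.4 and was negative with the arrays aligned at their medians. In the p53-responsive miR-34 list miR-34a had a log2 ratio of 0.60 and miR-34c was measured only in the injured artery, at least 2.69-fold higher (1.05-fold against the highest undetected signal). The hypoxia-responsive miR-210 had a log2 ratio of -0.06. In the adipose list the median of 3 members was 0.52, at percentile 65.3, and -0.076 with the control features aligned. Of the 8 epithelial miRNAs only miR-205 was measured, with a log2 ratio of 0.95, and the hepatocyte miR-122 was measured on neither array.

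**Figure D2:**
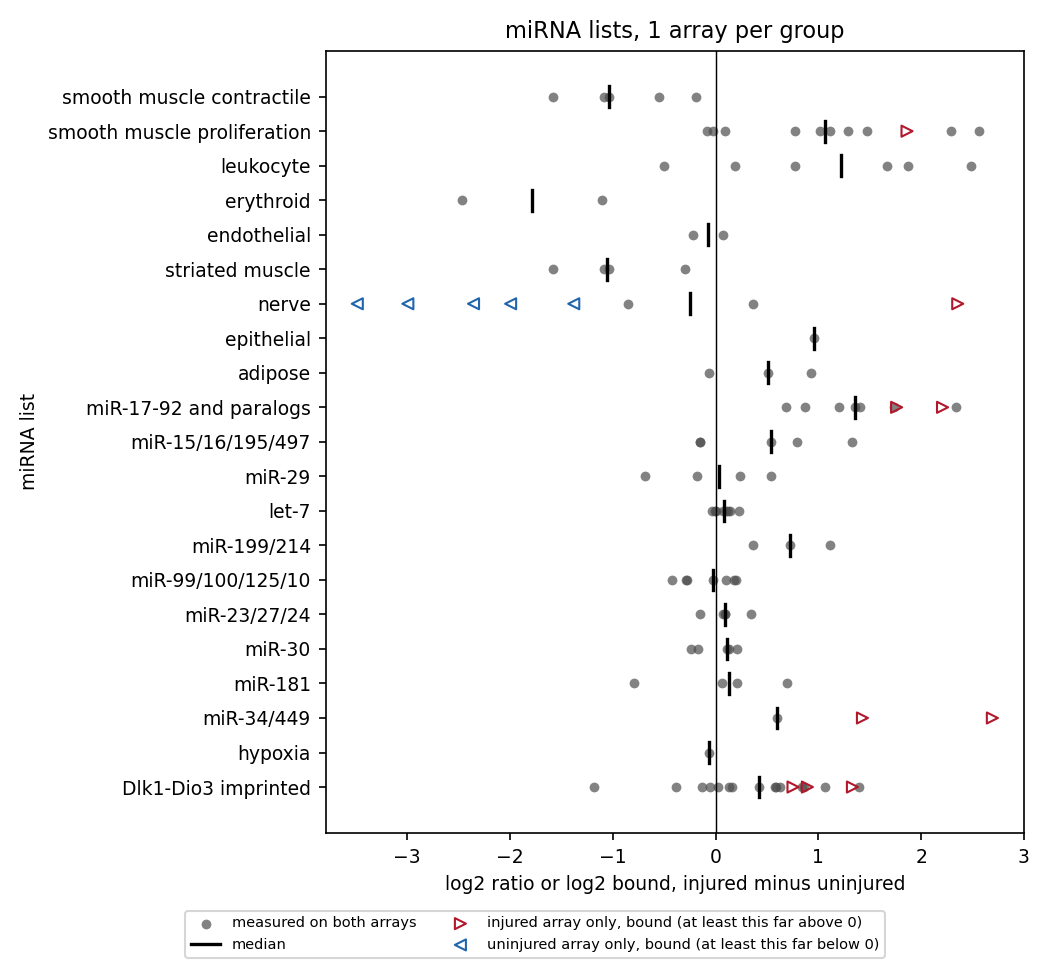
Each row is a miRNA list and each point a member, placed by its log2 ratio (injured minus uninjured); black bars are medians over members measured on both arrays and open triangles are bounds for members measured on 1 array. The contractile, erythroid and striated muscle lists lie below 0, the proliferation, leukocyte and miR-17-92 medians lie at 1.07, 1.22 and 1.35, and 5 nerve members have bounds below 0.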

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

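The tests in this part were chosen after the result was seen. Of the 22 control features, which took no part in the comparisons, 6 were detected on both arrays, and each was brighter on the injured array without scaling. The features named hur_1, hur_2, hur_4 and hur_6 were 1.24-fold, 1.39-fold, 1.34-fold and 1.65-fold brighter, the bright corner marker was 1.45-fold brighter and mr_1 was 1.94-fold brighter. What the hur and mr probes detect is not given in the sources used here. Their median log2 ratio was 0.50, against 0.05 for the 158 miRNAs measured on both arrays.

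A single brightness factor as the only difference between the arrays is argued against. The 20 brightest miRNAs by mean log2 signal had a median unscaled log2 ratio of 0.0025, with a median absolute deviation of 0.16. This lay below the control features by more than that deviation. A brightness factor together with lower miRNA levels would give the same values and is not excluded. The gap of 0.50 on the log2 scale may come from a smaller share of miRNA in the labelled RNA of the injured artery, which would lower all miRNA levels per unit of RNA, or from differences between these control probes. These cannot be told apart for these features, because the amounts of RNA put on each array are not given in the sources used here. No biological explanation was tested. If the control features were the right reference, the count of miRNAs at least 2-fold higher would be 7 and the count at least 2-fold lower would be 23.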

How the results depend on the processing

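The direction of the strongest ratios did not depend on the scaling, but the counts did, and with 1 array per group no alternative measures replicate error. The median shifts were at most 0.59 on the log2 scale. Except under quantile normalization, a ratio beyond 2-fold therefore could not change sign, so the kept directions add little support. The counts of miRNAs at least 2-fold higher and lower, 20 and 6, became 7 and 20 with the 75th percentile of all miRNAs, 8 and 16 with the medians aligned, 12 and 11 with quantile normalization and, added after the data were seen, 7 and 23 with the control features aligned. These scalings shifted the log2 ratios by medians of -0.50, -0.44, -0.30 and -0.59. The share of higher calls went from 76.9% to 25.9%, 33.3%, 52.2% and 23.3%. With no scaling or the authors' value table the counts were 17 and 7, and with a pseudocount 19 and 6. Restricting to the brighter 50% of miRNAs gave 9 and 3 by testing fewer miRNAs, and thresholds of 1.5-fold and 4-fold gave 40 and 16, and 4 and 1. The 6 lower calls were shared with every scaling, and the higher calls left under each scaling were all among the original 20. Detection at over 2 times the floor gave 189 miRNAs measured on both arrays, 18 miRNAs measured on the injured array only and 10 miRNAs measured on the uninjured array only. Under quantile normalization the cause was not tested; the other scalings apply 1 shift to all ratios. The medians of the adipose, miR-15/16, miR-29, let-7, miR-23, miR-30, miR-181 and Dlk1-Dio3 lists changed sign under at least 1 scaling, and those of the contractile, proliferation, leukocyte, erythroid, striated muscle and miR-17-92 lists under none.

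Aligning the control features lowered every list median by the same 0.59. The medians became -1.62 for contractile, 0.48 for proliferation, 0.63 for leukocyte, -2.38 for erythroid, -0.66 for endothelial, -1.65 for striated muscle, -0.84 for nerve, 0.36 for epithelial, -0.076 for adipose and 0.76 for miR-17-92. They became -0.055 for the miR-15/16 seed family, -0.56 for miR-29, -0.50 for let-7, 0.13 for the transcript of miR-199a and miR-214, -0.62 for the miR-99, miR-100, miR-125 and miR-10 families, -0.50 for the miR-23, miR-27 and miR-24 clusters, -0.48 for miR-30, -0.46 for miR-181, 0.0040 for the miR-34 list, -0.66 for miR-210 and -0.17 for Dlk1-Dio3. In the brighter miRNAs alone the erythroid median was -2.47 (miR-451 only), the nerve median -0.85 (miR-338 only) and the Dlk1-Dio3 median -1.18 (miR-494 only). Adding members measured on 1 array at their bound gave -1.69 for nerve and 1.43 for the miR-34 list, and -0.54 and 0.60 against the highest undetected signal. All other list medians moved by under 0.5, as did all named ratios except that of miR-322, which was 0.26 under quantile normalization, and those with the control features aligned, which all fell by 0.59. Of 17 bounds of named miRNAs that could be set against the highest undetected signal, 14 were smaller by over 0.5 on the log2 scale. With dim signals raised to that level, also added later, 19 miRNAs were at least 2-fold higher and 6 lower. Detection from the value table and a filter on signal error were not run, because the table has no flags and the files have no errors. No paired analysis was possible because each group holds 1 array, and leaving out a replicate was not possible for the same reason.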

Other observations

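The prediction on neighbouring genes was written before its result; the other tests in this part were chosen after the values were seen, as were miR-503, miR-542-3p, miR-322* and miR-212, which fall outside the naming rule. Several miRNAs whose genes neighbour each other on the rat X chromosome had higher signals in the injured artery, but they are not one of the fixed lists and were not tested as a set. miR-503, which targets cell-cycle regulators, was at least 4.93-fold higher, miR-450a at least 3.53-fold, miR-542-3p at least 3.05-fold and miR-322* at least 1.71-fold, all measured only on the injured array, and miR-322, measured on both, was 1.73-fold higher, with a log2 ratio of 0.20 with the control features aligned. Their neighbours miR-351 and miR-542-5p were measured on neither array. Against the highest undetected signal the bounds were 1.91-fold for miR-503, 1.93-fold for miR-450a and 1.18-fold for miR-542-3p, with none above 1 for miR-322*.

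miR-132 and miR-212, which are neighbours, had different ratios. miR-132 was measured only on the injured array, at least 5.51-fold higher with signals of 0.711 and 17.8, and at least 2.14-fold higher against the highest undetected signal. miR-212 was measured on both arrays with signals of 129 and 162, a ratio of 1.33-fold. miR-494 stood apart from its neighbours in the Dlk1-Dio3 region: its log2 ratio was -1.18, against 1.40 for miR-379, 0.86 for miR-376a, 0.84 for miR-376b-3p, 0.63 for miR-300-3p and -0.13 for miR-329. It was also far brighter, with signals of 1111 (uninjured) and 461 (injured), while none of these neighbours exceeded 34.3, the injured signal of miR-379. Whether its probe reads only miR-494 was not tested.

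Shared transcripts were tested as a general hypothesis. Over 50 pairs of miRNAs whose genes lie within 10 kb, among the 135 miRNAs with 1 known gene, log2 ratios differed by a median of 0.47, against 0.61 for random pairs. This lay at percentile 9.06 of 10000 random sets of pairs, so the predicted closeness was not met; without miR-494, 45 pairs had a median of 0.45 at percentile 6.52. Both arms of 1 hairpin differed by a median of 0.40 over 18 pairs, at percentile 9.50. Such arms share a transcript and yet were no closer by this measure, so the test cannot decide for or against shared transcripts. The neighbouring pairs also reused miRNAs, while the random pairs were drawn independently.

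The source of the higher leukocyte miRNAs, with white cells in the injured wall as one hypothesis, was not tested directly. More residual whole blood in the injured sample is argued against, because the red-cell miRNAs were lower, with a median log2 ratio of -1.79. That median rests on miR-451 and miR-144 from 1 transcript. It does not track white cells held on the wall without red cells, so these stay open. A lower share of smooth muscle alone would raise endothelial miRNAs alike, and the leukocyte median exceeded the endothelial one by 1.30. That gap cannot decide the question, because the balloon itself strips the endothelium and the endothelial list holds only miR-126 and miR-126*. Loss of endothelium to the balloon, a second change, was not tested. A difference between animals or arrays cannot be told apart from injury, because there was 1 array per group.

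The neuronal miRNAs missing from the injured array are a candidate for follow-up. Chance among dim signals stays open: the list median with bounds was -1.69, below all random lists matched on signal, and -0.54 at percentile 0.185 against the highest undetected signal, but miR-9 and miR-129*, with uninjured signals under that level, set the first median and miR-9 helps set the other. Nerve or ganglion tissue caught with the uninjured artery may account for them, and so may loss of wall innervation after injury. The glial miRNAs did not decide it: miR-338 had a log2 ratio of -0.85 while miR-219-5p was at least 2.36 log2 units higher after injury (at least 3.71-fold against the highest undetected signal). Both remain open, as the labels do not say how far the surrounding tissue was removed.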
